A study of Homo sapiens with 4 samples.

How the data were processed

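Poly(A) RNA from SK-N-BE(2) cells was profiled in 4 libraries, 2 with hairpins against MAB21L2 and 2 with a negative-control hairpin. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq RNA kit, which does not mark strand, and sequenced on a NovaSeq instrument. Per the submitters' processing notes, STAR 2.7.10a, StringTie 2.1.7, DESeq2 1.40.2 and the build hg38 were used, with no role or order stated. The counting program, its strand setting and the annotation are not given in the sources used here.

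The authors deposited 1 table of 20040 genes for the whole series. Per the file headers it holds raw counts per gene and library, which are whole numbers with different totals per library. It also holds FPKM values that the authors computed, with 1 of the 4 headers spelled PFKM and read here as FPKM because its values have the same scale. The authors' log2 fold change, p-value and FDR for knockdown against control stand beside them, per the file headers. FDR was given for 15377 genes and left empty for 4663. The smallest count in any library was 1 and 0 genes had a count of 0, so genes without counts in any 1 library are not listed and a gene silenced completely could not be seen. Versioned gene IDs of 20034 genes are found in GENCODE release 29, from which positions, lengths and GC content (of the longest transcript) were taken. The other 6 entries are tRNAs without a gene name; they held at most 0.00014% of a library's counts and were left out of totals and tests. Current symbols were matched for 19896 genes by ID, so that lists could be matched by older or newer names.

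Samples were grouped by their titles, and groups, tests, alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. The rule took MAB21L2, LRBA and the measured Mab-21 family first. It then took the 10 largest rises and the 10 largest falls among called genes with a symbol other than a clone or locus name (LINC and LOC names included), a mean of at least 5 CPM and both knockdown libraries on the same side of both controls. Up to 4 called members with the smallest adjusted p were added from each list. Not every gene the rule picks is described, and 18 of the 20 largest changes are. Genes named outside the rule are marked as such.

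Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr (17425 tested, 2609 not tested), scaled by TMM and compared with the quasi-likelihood test, without a block. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, and at least 2-fold means an absolute log2 fold change of 1 or more. TMM factors were 0.994 and 0.991 in control replicates 1 and 2 and 1.007 and 1.008 in knockdown replicates 1 and 2. Standard errors are the log2 fold change divided by the square root of the test's F. The common biological coefficient of variation was 0.0705. Totals ran from 31211419 to 33923036 counts per library. Counts of the replicates were compared before averaging, and chi-square per degree of freedom was 10.1 in the control pair and 3.63 in the knockdown pair, so both pairs differed by more than sampling noise.

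Lists were tested with limma 3.58.1 (camera on log2 CPM with prior count 2, preset correlation 0.01, 28 list tests adjusted together), again with a correlation estimated from the 4 libraries, and with fry, which asks whether a list's genes move one way and does not compare them with other genes. No list kept an adjusted p below 0.05 with the estimated correlation.

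Alternatives fixed beforehand were RLE and upper quartile scaling, DESeq2 1.42.0, no filter on low counts, a mean of at least 5 CPM, a replicate block, each library left out in turn, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1. Fold changes on the FPKM scale are those of log2(FPKM + pseudocount) and understate changes of low genes. After seeing the GC trend of control replicate 1, a correction was added that removed from each library a smooth trend over GC content and log length (natural splines with 5 degrees of freedom each, fitted on genes of at least 1 CPM), alone, with the replicate block and without control replicate 1. With it the coefficient of variation was 0.0475.

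The edgeR test, with and without the GC and length correction, and camera at the preset correlation were tested on simulated data drawn from the real means and library sizes of knockdown against control. The other tests were not simulated. In 17378 simulated genes edgeR recovered 30% of 50 genes changed 1.25-fold, 78% at 1.5-fold, 92% at 2-fold and 98% at 4-fold, with 8 calls among unchanged genes. A simulated GC trend in 1 control library, with no gene changed, gave 0 calls among 17340 genes with and without the correction. The simulated spread was taken from the uncorrected fit, which already held the trend of control replicate 1. These 0 calls therefore do not show that such a trend makes no false calls. With the correction 36%, 84%, 86% and 96% of changed genes were recovered under that trend at 1.25-fold, 1.5-fold, 2-fold and 4-fold (17364 genes). Camera found 5 of 5 shifted lists and 0 of 25 unchanged lists among 17344 simulated genes. Genes were simulated independently of each other, so this does not test camera on lists whose genes vary together. Figures were drawn with matplotlib 3.10.9.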

Results

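RNA from SK-N-BE(2), an established human neuroblastoma cell line that expresses high levels of MYCN, was sequenced after delivery of short hairpin RNAs against MAB21L2 or of a negative-control hairpin. Each group held 2 libraries, 4 in all. MAB21L2 encodes a protein of the Mab-21 family that is needed in vertebrate eye development, and the series title places it under a super-enhancer and links it to neuroblastoma progression. The question of the comparison was therefore which transcripts differ when MAB21L2 is lowered. The deposited counts summed to 31211419 and 32471269 in knockdown replicates 1 and 2 and to 33923036 and 32797724 in control replicates 1 and 2. Mitochondrially encoded genes took 5.91% and 6.05% of the counts in the knockdown libraries and 7.16% and 6.68% in the control libraries, and MT-CO1 was the most abundant gene in all 4. The labels do not say whether the replicates of a group came from separate cultures or whether both knockdown libraries carried the same hairpin, so p-values measure only the spread between these libraries, which may be technical.

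Control replicate 1 stood apart from the other 3 libraries in its relation to GC content. Across 11129 genes, which are not independent replicates, the log2 difference of control replicate 2 from control replicate 1 had a Spearman correlation of 0.681 with transcript GC content, against -0.195 for the knockdown pair. From the bin of genes lowest in GC to the highest, among 10 bins of equal size, the median difference between the controls ran from -0.177 to 0.188 on the log2 scale, and that of knockdown from control ran from -0.107 to 0.115. Some counts below are therefore also given with a GC and length correction, chosen after the data were seen, or without control replicate 1.

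**Figure D1:**
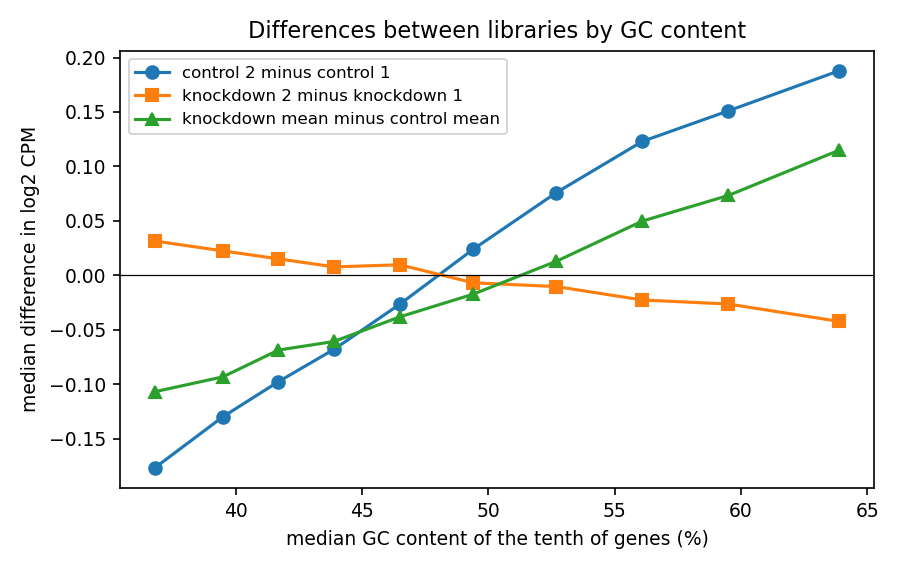
Median difference in log2 CPM (counts-per-million; vertical axis) for genes in 10 bins of equal size by transcript GC content in percent (horizontal axis), for control replicate 2 minus 1, knockdown replicate 2 minus 1, and the knockdown mean minus the control mean. The control pair runs from -0.177 to 0.188, the knockdown pair stays close to 0, and the group difference runs from -0.107 to 0.115.

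MAB21L2, the targeted gene, was lower in both knockdown libraries than in both controls. Its level was 87.4 ± 4.48 counts-per-million (CPM; SD, n = 2) in the control and 38.0 ± 1.84 CPM (n = 2) in the knockdown, a 2.30-fold fall (log2 fold change -1.20, SE 0.0859, edgeR adjusted p = 5.15e-12). The raw counts were 3052 and 2736 in the controls and 1153 and 1285 in the knockdowns. Its paralog MAB21L1 also fell, from 249 ± 6.84 to 179 ± 0.877 CPM (log2 fold change -0.47, adjusted p = 3.63e-06). MAB21L2 (ENSG00000181541.5) lies on chromosome 4 at 150581922 to 150584693 of hg38 as a single exon of 2772 bases, 1077 of them coding and 1695 untranslated. It sits within LRBA, a gene of vesicle trafficking on the opposite strand, and 1491 of its bases are also annotated as exon of an LRBA transcript. LRBA stood at 249 ± 3.44 CPM in the control and 275 ± 4.67 CPM in the knockdown (log2 fold change 0.14, adjusted p = 0.124). MAB21L1 (ENSG00000180660.7, chromosome 13, 35474182 to 35477209) lies within NBEA, a related trafficking gene, again on the opposite strand, and shares 89 of its 3028 exonic bases with it. NBEA rose from 97.5 ± 2.59 to 133 ± 1.6 CPM (log2 fold change 0.45, adjusted p = 2.30e-05). The library kit does not mark strand, so reads of these overlapping genes cannot be told apart where they share bases. LRBA passed the test, as higher, when control replicate 1 (adjusted p = 0.00734) or control replicate 2 (0.0325) was left out, with upper quartile scaling (0.0343) and with the GC and length correction (1.14e-06).

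**Figure D2:**
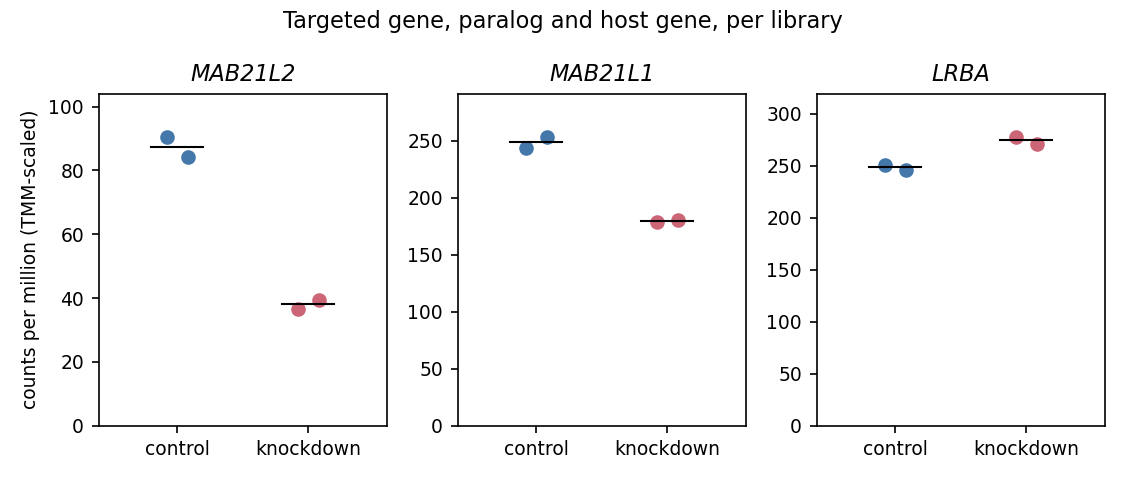
CPM (TMM-scaled, linear axes from 0) of MAB21L2, MAB21L1 and LRBA in each of the 2 control and 2 knockdown libraries, with a bar at each group mean. The MAB21L2 means are 87.4 in the control and 38.0 in the knockdown, the MAB21L1 means are 249 and 179, and the LRBA means are 249 and 275.

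Across the transcriptome, 3863 of 17425 tested genes (22.2%) differed between the groups by edgeR's quasi-likelihood test, 1711 higher and 2152 lower in the knockdown. Most changes were small, with a median of 1.37-fold among the called genes. Of those, 502 differed by at least 2-fold, 266 higher and 236 lower. The larger side of this split turned with a mean of at least 5 CPM (49 higher and 102 lower), with DESeq2 (163 and 200), with limma on log2(FPKM + 1) (28 and 56) or log2(FPKM + 0.1) (77 and 130), without knockdown replicate 1 (163 and 209) or 2 (153 and 210), and by a small margin with the GC and length correction and the replicate block (245 and 247). Protein-coding genes made up 3514 of the 3863. The authors' deposited table lists 3326 genes at an FDR below 0.05, 1354 higher and 1972 lower, and 3315 of these (99.7%) were also called here, all in the same direction. Leaving out knockdown replicate 1 or 2 lowered the count to 1670 or 1744, and limma on log2(FPKM + 1) gave 1892. The count was 5193 with the GC and length correction and 4370 without control replicate 1. Upper quartile scaling turned the split to 2181 higher and 1701 lower, 56.2% higher against 44.3%, while moving the median of all genes by only 0.05 on the log2 scale.

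Among the 10 largest falls were genes of the extracellular matrix and cell adhesion. ADAMTS9, a secreted protease that cleaves proteoglycans, fell 4.54-fold, from 171 ± 4.70 to 37.6 ± 1.01 CPM (log2 fold change -2.18, SE 0.0794, adjusted p = 1.14e-18). COL3A1, a fibrillar collagen chain, fell 4.34-fold from 39.6 ± 0.988 to 9.14 ± 0.184 CPM, and LUM, the collagen-binding proteoglycan lumican, fell 3.70-fold from 163 ± 19 to 44.0 ± 2.30 CPM. NEDD9, a scaffold of focal adhesions, fell 3.99-fold, ITGA9, an integrin chain, 3.27-fold, and PLXNA2, a semaphorin receptor, 3.19-fold. DDIT4L, an inhibitor of mTOR signalling, had the largest fall by rule (log2 fold change -2.25), at a low level of 8.35 ± 0.559 CPM in the control. LHFPL6 and RNF152, a lysosomal ubiquitin ligase, were also among the 10 largest falls, of which 9 are described, with log2 fold changes of -1.76 and -1.75. ADAMTS9, ITGA9, LHFPL6 and DDIT4L each overlap another annotated gene in the deposited table.

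Among the genes that rose most, SAMD11, a SAM-domain protein, went from 10.9 ± 1.64 to 56.8 ± 0.542 CPM, a 5.22-fold rise (log2 fold change 2.38, SE 0.111, adjusted p = 4.98e-16). ABCA12, a lipid transporter, rose 4.04-fold to 33.3 ± 1.62 CPM. FEV, an ETS transcription factor of serotonergic neurons, rose 2.97-fold from 16.8 ± 1.44 to 50 ± 3.19 CPM. KIAA1324 (4.28-fold), the acid-sensing channel subunit ASIC4 (3.89-fold), the metalloproteinase PAPPA2 (3.83-fold), the epithelial adhesion gene EPCAM (2.93-fold), the kinase DYRK1B (2.92-fold) and the adhesion gene FLRT1 (2.88-fold) were also among the 10 largest rises, of which 9 are described. SAMD11 overlaps NOC2L, KIAA1324 overlaps C1orf194 and FLRT1 overlaps MACROD1, and reads from shared bases cannot be assigned between them. Each of these 18 genes passed the test with every library left out in turn and with the GC and length correction.

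**Figure D3:**
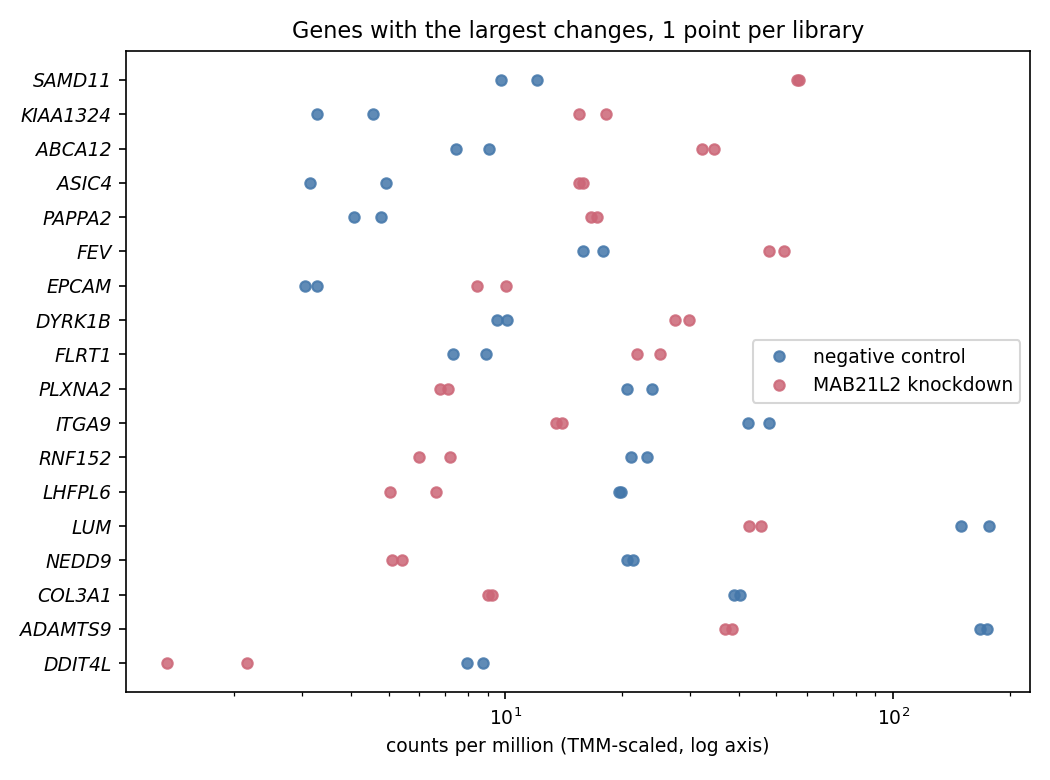
CPM (TMM-scaled, logarithmic horizontal axis) of the 9 genes described among the 10 largest rises and the 9 among the 10 largest falls, 1 point per library, 2 control and 2 knockdown libraries per gene. The knockdown points lie beyond both control points for every gene shown, for example 56.8 against 10.9 CPM on average for SAMD11 and 37.6 against 171 CPM for ADAMTS9.

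The 2 cell cycle lists had members lower in the knockdown and 0 higher. In the G2/M list, 27 of 30 measured members fell and 0 rose (28 fell adjusted over the list alone), with a median log2 fold change of -0.445. The mitotic kinesin KIF20A fell from 202 ± 5.32 to 117 ± 3.02 CPM, the proliferation marker MKI67 from 803 ± 0.292 to 522 ± 20.4 CPM, the centromere gene CENPF from 607 ± 29.9 to 404 ± 4.02 CPM, and the mitotic kinase CDK1 from 193 ± 25.1 to 127 ± 0.876 CPM. In the G1/S and DNA replication list, 14 of 30 members fell and 0 rose (14 adjusted over the list alone), with a median of -0.225. GINS2, part of the replicative helicase, fell 2.27-fold from 83.9 ± 7.20 to 36.9 ± 4.08 CPM, cyclin E gene CCNE1 fell 1.66-fold, the replication licensing gene CDC6 1.39-fold and the sliding clamp PCNA 1.35-fold. By limma's camera with its preset correlation, adjusted p was 3.58e-21 for G2/M and 2.38e-08 for G1/S. Both calls were lost otherwise, with adjusted p = 0.288 (G2/M) and adjusted p = 0.229 (G1/S) with an estimated correlation. After the GC and length correction the medians were -0.398 with 29 falls and -0.206 with 23 falls. The G1/S count was 7 without knockdown replicate 1, 8 without knockdown replicate 2 and 22 without control replicate 1, while the G2/M count was 20, 18 and 28 in the same order.

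Of 29 measured matrix and invasion genes, 20 fell and 0 rose (20 adjusted over the list alone), with a median log2 fold change of -0.489. The adhesion gene CDH11 fell 2.45-fold from 88.4 ± 1.11 to 36.2 ± 0.732 CPM, LOXL2, a collagen crosslinking enzyme, fell 2.67-fold from 32.7 ± 2.00 to 12.2 ± 1.73 CPM, TIMP2, a metalloproteinase inhibitor, fell 1.67-fold from 476 ± 2.25 to 285 ± 9.69 CPM, and the basement membrane collagen COL4A1 fell 2.16-fold. Markers of the mesenchymal state of neuroblastoma cells, a more migratory cell state, were lower for 12 of 27 measured members and higher for 0 (14 lower adjusted over the list alone), with a median of -0.401. COL3A1 led that list, followed by the collagen COL5A1 (1.95-fold, 50.8 ± 3.99 to 26.0 ± 0.0710 CPM), the galectin LGALS1 (1.64-fold) and the matrix protein SPARC (1.58-fold, 188 ± 10.4 to 119 ± 4.28 CPM). Camera gave adjusted p = 6.07e-12 for the matrix list and 5.59e-08 for the mesenchymal list, against adjusted p = 0.207 and adjusted p = 0.288 with an estimated correlation. After the GC and length correction 20 matrix and 13 mesenchymal genes were lower, and without control replicate 1 the numbers were 18 and 15.

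Of 30 measured transcripts for cytosolic ribosomal proteins, 29 rose and 0 fell (29 adjusted over the list alone), with a median log2 fold change of 0.351, or 1.27-fold. RPS3 went from 2929 ± 153 to 3947 ± 93.4 CPM, RPS27 from 517 ± 13.9 to 740 ± 24.8 CPM, RPL30 from 206 ± 2.02 to 308 ± 8.36 CPM and RPS23 from 250 ± 10.2 to 367 ± 15.8 CPM. Ribosomal protein genes have many processed pseudogenes, so their counts could be split by the authors' counting and are uncertain to that extent. Messenger RNAs encoded by the mitochondrial genome went the other way, with 10 of 13 lower and 0 higher (11 lower adjusted over the list alone) and a median of -0.241. This list and the histone list below were fixed beforehand as signs of RNA quality. Whether RNA quality differed between the groups was not tested. MT-CO3, a subunit of cytochrome c oxidase, fell 1.31-fold from 8880 ± 958 to 6763 ± 230 CPM, and MT-CO2, of the same enzyme, fell 1.24-fold. Camera gave adjusted p = 5.59e-24 for the ribosomal list and 4.50e-05 for the mitochondrial list, against adjusted p = 0.197 and adjusted p = 0.557 with an estimated correlation. With the GC and length correction 30 ribosomal genes rose (median 0.317) and 12 mitochondrial mRNAs fell. Without knockdown replicate 1 the counts were 19 and 1, without knockdown replicate 2 they were 20 and 3, and the MT-CO2 call was lost without knockdown replicate 1.

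**Figure D4:**
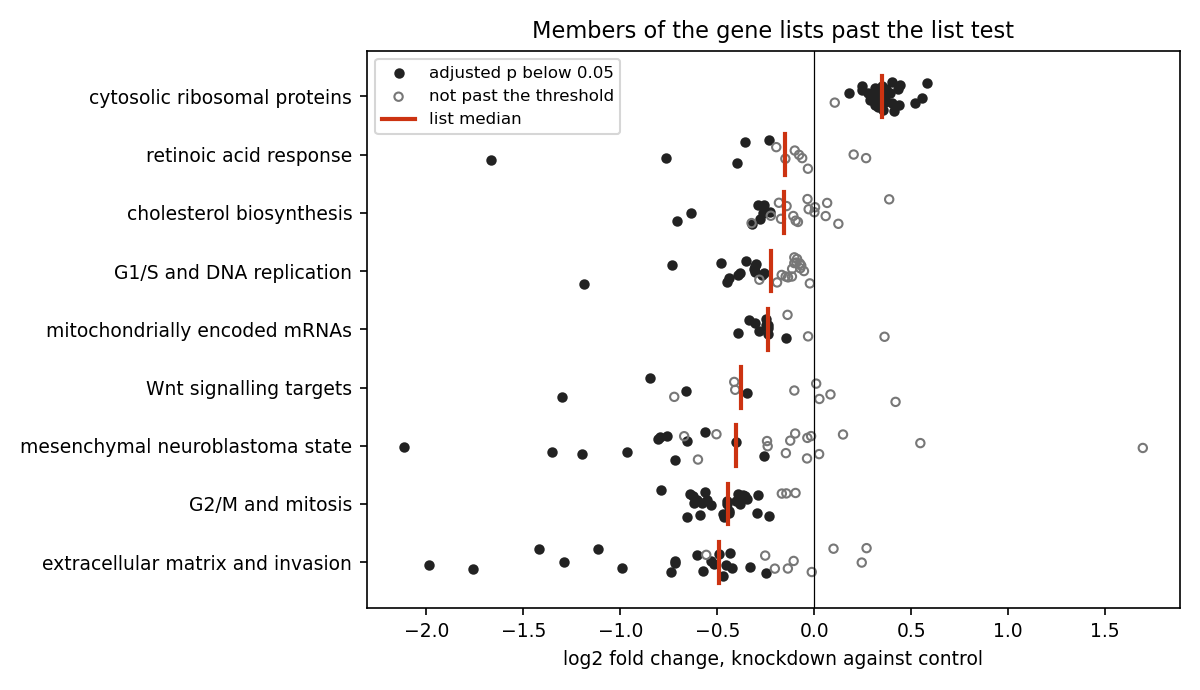
Log2 fold change of knockdown against control (horizontal axis) for each measured member of the 9 gene lists with a camera adjusted p below 0.05 at the preset correlation, with called genes filled and a red bar at each list median. The ribosomal protein list has its median at 0.351, with 29 of 30 members called higher, and the other 8 lists have medians from -0.489 to -0.149.

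In the lists of Wnt targets, cholesterol synthesis and retinoic acid response, a minority of members passed the test. Of 12 measured Wnt targets, 4 fell and 0 rose (5 fell adjusted over the list alone; median -0.376). These were the Wnt antagonist DKK1 (184 ± 6.91 to 102 ± 5.72 CPM), the growth factor BMP4 (16.4 ± 0.726 to 6.66 ± 1.38 CPM), the R-spondin receptor LGR5 (143 ± 12.1 to 90.7 ± 2.86 CPM) and the Wnt receptor FZD7 (154 ± 6.11 to 122 ± 5.85 CPM). The feedback target AXIN2, named after its value was seen, had a log2 fold change of 0.01. Of 24 cholesterol genes, 8 fell and 0 rose (10 fell and 1 rose adjusted over the list alone; median -0.157), led by the synthase HMGCS1 (1.55-fold) and the sterol carrier STARD4 (1.63-fold). Of 13 retinoic acid genes, 5 fell and 0 rose (5 adjusted over the list alone; median -0.149), led by the transglutaminase TGM2 (3.17-fold, 24.1 ± 2.19 to 7.61 ± 0.854 CPM) and the retinoid-binding gene CRABP1 (1.70-fold). Camera gave adjusted p = 0.00331, 0.00454 and 0.00599 in that order, against adjusted p = 0.288, adjusted p = 0.288 and adjusted p = 0.425 with an estimated correlation. The Wnt median was -0.187 without control replicate 2 and -0.250 without knockdown replicate 1, and the retinoic acid median was -0.271 without knockdown replicate 1 and -0.234 without control replicate 1. FZD7 was not called without knockdown replicate 2. Without knockdown replicates 1 and 2 in turn, 2 and 2 cholesterol genes and 3 and 2 retinoic acid genes fell, and without control replicate 2, 2 cholesterol genes rose and the retinoic acid list missed the threshold (adjusted p = 0.055).

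Neuroblast identity genes changed in both directions. Among 22 adrenergic transcription factors, which maintain the sympathetic neuroblast state, 3 rose and 8 fell (4 and 9 adjusted over the list alone). GATA2 rose from 187 ± 16.8 to 313 ± 2.29 CPM and TFAP2B from 298 ± 7.49 to 395 ± 6.97 CPM, while KLF7 fell from 296 ± 13.8 to 216 ± 5.56 CPM. Of 20 catecholamine and neuroendocrine genes, 5 rose and 5 fell (5 and 5 adjusted over the list alone). The granule proteins CHGA (448 ± 46.3 to 688 ± 0.505 CPM) and CHGB (243 ± 3.49 to 344 ± 19.2 CPM) rose, while SCG2, another granule protein, and GCH1, which makes a cofactor of catecholamine synthesis, fell 1.36-fold and 1.6-fold. Neurite and synapse genes had 3 of 30 members higher and 10 lower (3 and 11 adjusted over the list alone). The peripheral neuron filament PRPH rose from 57.4 ± 3.97 to 116 ± 2.09 CPM, whereas the neuronal RNA-binding gene ELAVL4 (201 ± 16 to 106 ± 7.76 CPM), the neurofilament NEFM (571 ± 6.34 to 372 ± 0.238 CPM) and the microtubule regulator STMN2 (1140 ± 81.7 to 751 ± 15.9 CPM) fell. Camera gave adjusted p of 0.399, 0.802 and 0.172 for the 3 lists. The neurite list passed, as lower, without control replicate 1 (adjusted p = 0.00252) or control replicate 2 (adjusted p = 0.016), and the genes lower in the 3 lists numbered 3, 2 and 5 without knockdown replicate 1 and 4, 4 and 6 without knockdown replicate 2. Without control replicate 2, 5 adrenergic and 9 neurite genes rose, and with either knockdown replicate left out 1 neurite gene rose.

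Signalling genes also split. Of 16 neurotrophin and receptor kinase genes, 2 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.650). The neurotrophin receptor NGFR rose 2.51-fold from 15.2 ± 3.94 to 38.2 ± 1.54 CPM. The receptor kinase ALK (103 ± 11.2 to 65.1 ± 2.60 CPM), the growth factor PTN (1.45-fold) and FGFR2 (1.83-fold) fell. Of 26 genes of BMP and TGF-beta signalling, 4 rose and 7 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.340). The BMP-induced repressors ID3 (97.1 ± 6.16 to 171 ± 0.315 CPM) and ID2 (32.1 ± 0.382 to 55.8 ± 0.689 CPM) rose, while the ligand BMP4 and the TGF-beta-induced matrix gene TGFBI (2.62-fold) fell. Among 23 immediate early genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.457). EGR1 was up 1.96-fold from 21 ± 3.15 to 41.2 ± 2.48 CPM and KLF6 was down 1.44-fold. With the GC and length correction 5 immediate early genes rose and 6 fell. Without knockdown replicate 1, 1 immediate early gene rose and 1 fell, without knockdown replicate 2, 3 rose and 1 fell, and without control replicate 1, 5 rose and 4 fell. Without control replicate 2, 4 receptor kinase genes rose.

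Neither list of MYC target genes passed camera. In ribosome biogenesis, 3 of 24 members rose and 0 fell (2 rose adjusted over the list alone; camera adjusted p = 0.340), among them the polymerase I factor UBTF (167 ± 4.73 to 212 ± 0.663 CPM). In metabolism, 4 rose and 9 fell of 24 (6 and 10 adjusted over the list alone; camera adjusted p = 0.399), among them the serine synthesis gene PSAT1, 1.30-fold lower, and the nucleotide synthesis gene IMPDH2, 1.28-fold higher. Of 30 nuclear-encoded respiratory chain genes, 5 rose and 1 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.340), with CYC1 at 199 ± 19.2 and 242 ± 9.87 CPM. With the GC and length correction 7 respiratory chain genes rose and 6 fell. All members of the ribosome biogenesis and respiratory chain lists lost their calls without knockdown replicate 1, and also without knockdown replicate 2. In the metabolism list, 0 rose and 2 fell without the former, and 1 rose and 1 fell without the latter. Without control replicate 2, 9 metabolism genes rose and 11 fell, and 10 respiratory chain genes rose and 5 fell, against 7 and 2 of the latter without control replicate 1. In ribosome biogenesis 4 rose in both cases, and 1 fell without control replicate 1 and 2 without control replicate 2.

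Stress and death pathways gave scattered calls. Of 20 p53 targets, 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.219), with the stress genes TP53INP1 (1.80-fold) and SESN2 (1.75-fold) higher and the death receptor TNFRSF10B 2.44-fold lower. Among 22 apoptosis regulators, 2 rose and 5 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.212), with the caspase activator APAF1 (49.1 ± 1.71 to 28.5 ± 0.279 CPM) and PMAIP1 (1.52-fold) lower. Hypoxia and glycolysis genes had 4 of 30 higher and 6 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.375), led by the glucose transporter SLC2A3, 2.96-fold lower. In the ATF4 list 4 of 26 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.457), with SESN2 again among the former and PSAT1 among the latter. The unfolded protein response list had 0 of 18 higher and 2 lower, HSP90B1 and PDIA4 (0 adjusted over the list alone; camera adjusted p = 0.802). In the type I interferon list, written because hairpins can induce that response, 0 of 16 rose and 4 fell (4 adjusted over the list alone; camera adjusted p = 0.674), among them IFI6 (17.4 ± 3.79 to 12.5 ± 0.443 CPM). Without knockdown replicate 1 the numbers lower were 1 for p53, 2 for apoptosis, 2 for hypoxia, 0 for ATF4, 0 for the unfolded protein response and 0 for interferon, and without knockdown replicate 2 they were 1, 3, 2, 1, 0 and 1. In the same order they were 2, 6, 10, 5, 2 and 2 without control replicate 1, and 3, 8, 9, 6, 2 and 2 without control replicate 2. The numbers higher were 3, 2, 1, 2, 0 and 0 without knockdown replicate 1, 3, 0, 1, 2, 0 and 0 without knockdown replicate 2, 4, 2, 7, 6, 1 and 0 without control replicate 1, and 6, 4, 5, 8, 3 and 1 without control replicate 2. IFI6 was not called without control replicate 2 (adjusted p = 0.222) or either knockdown replicate.

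No list of markers of other cell types besides the mesenchymal list passed camera. Schwann lineage markers had 1 of 6 higher and 2 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.802), the higher one being NGFR and the lower ones PMP22 (36.2 ± 1.28 to 20.2 ± 1.99 CPM) and EDNRB (0.511 CPM in the control). Epithelial markers had 1 of 5 higher, EPCAM (3.16 ± 0.153 to 9.26 ± 1.13 CPM), and 1 lower, KRT18, at 0.513 CPM in the control (1 and 1 adjusted over the list alone; camera adjusted p = 0.856). That list's median was -0.446 and its mean -0.370, while camera gave its direction as up, and as down with upper quartile scaling. KRT18 lost its call with any library left out, while KRT19 was called lower without knockdown replicate 1 (adjusted p = 0.0232) and CLDN4 without control replicate 1 (adjusted p = 0.00304), both named after their values were seen, and EDNRB lost it without either knockdown replicate or control replicate 1. Of the blood cell markers only PTPRC, named after its value was seen, was tested, with a log2 fold change of -0.17 (16.9 CPM in the control, adjusted p = 0.373), so no list test was made. Replication-dependent histone transcripts, which mostly lack a poly(A) tail, had 3 of 16 members higher and 0 lower (3 adjusted over the list alone; median 0.350; camera adjusted p = 0.144; 1 without knockdown replicate 1, and 2 without knockdown replicate 2 or control replicate 2), and limma on log2(FPKM + 1) put that list past the threshold (adjusted p = 0.00987). In the list of Mab-21 family and host genes 1 of 5 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.340), and its member CGAS, the DNA sensor, named after its values were seen, was near the floor at 0.688 ± 0.537 and 0.378 ± 0.275 CPM (adjusted p = 0.385).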

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

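Tests with the GC and length correction were chosen after the data were seen; the others were fixed beforehand. The MAB21L2 log2 fold change was negative and past the threshold under all 15 alternatives, from -1.26 to -1.09. The 3863 genes changed between MAB21L2 knockdown and negative control became 1670 to 5325 when 1 library was left out, lowest without knockdown replicate 1 and highest without control replicate 2. With 1 library of a group left, that library is assumed to vary like the other group's. Without a knockdown library the spread is therefore estimated from the control pair alone. That pair differed more than the knockdown pair (chi-square per degree of freedom 10.1 against 3.63). Calls lost in those fits need not mean smaller changes. Limma on FPKM gave 1892 (log2(FPKM + 1)) and 1884 (log2(FPKM + 0.1)), with fewer genes tested (12699), and 29.2% and 29% of the called genes higher. No further scaling between libraries was applied in these fits. Their median log2 fold change of all genes was -0.053 and -0.062, against 0.003 in the reported fit. Whether this shift accounts for the lower share was not tested. For genes changed at least 2-fold, 502 in the reported fit, leaving out a library gave 363 to 547, the filter at a mean of 5 CPM gave 151, since it tests fewer genes, and FPKM gave 84 and 207 at pseudocounts of 1 and 0.1, the former shrinking low genes. DESeq2 called 3326 genes, 3315 of them shared. The replicate block called 3493 genes, 3442 of them shared; the 2 pairs share only a number (correlation of deviations -0.028 across genes). The GC and length correction called 5193 genes, 4909 with the replicate block and 4637 without control replicate 1, and shared 3640, 3567 and 3238 with the 3863.

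All 9 lists past camera's threshold lost their call with an estimated correlation. Adjusted p was then 0.288 for G2/M, mesenchymal, cholesterol and Wnt genes, 0.229 for G1/S, 0.207 for matrix, 0.197 for ribosomal, 0.425 for retinoic acid and 0.557 for mitochondrial genes. With the GC and length correction as well it was 0.14 for mesenchymal, G1/S, matrix and mitochondrial genes, 0.185 for G2/M, 0.192 for cholesterol, 0.225 for Wnt, 0.136 for ribosomal and 0.381 for retinoic acid genes. With 4 libraries a correlation estimated within groups rests on 2 degrees of freedom. Fry gave 0.0683 for retinoic acid and mitochondrial genes and 0.0516 for cholesterol genes. The retinoic acid list also missed the threshold with FPKM (0.0758 and 0.0735) and ranged from 0.000583 to 0.055 with 1 library left out. The other 8 lists passed under each remaining alternative. The replicate block changed no list call. Of the lists not past the threshold, 6 had the direction given by camera or fry reversed in 20 tests, 0 of them with adjusted p below 0.05; the cause was not tested. This is the direction of the test, not of the list median, which stayed below 0 for receptor kinase genes in both cases and for Schwann markers in all but the filter at 5 CPM (2 genes). For catecholamine genes it became down without knockdown replicate 2 (0.993), with fry (0.666) and with the GC and length correction, alone (0.981), with the replicate block (0.955) and with an estimated correlation (0.988). For Schwann markers it became up at 5 CPM (0.773), with the replicate block (0.824), without control replicates 1 (0.87) and 2 (0.638), with FPKM (0.985 and 0.996) and with the GC and length correction without control replicate 1 (0.967). For epithelial markers it became down with upper quartile scaling (0.957), no filter (0.867) and without knockdown replicate 1 (0.811), for receptor kinase genes up without knockdown replicate 2 (0.993) and control replicate 2 (0.962), for the unfolded protein response down with fry (0.884) and, at 0.967, with the correction without control replicate 1, where for BMP and TGF-beta genes it became up at 0.967. With 1 library left out adjusted p ranged from 0.257 to 0.993 for catecholamine genes, 0.485 to 0.861 for epithelial markers and 0.175 to 0.993 for receptor kinase genes. No named gene reversed. Of 119 named genes, 32 lost their call without knockdown replicate 1 and 31 without knockdown replicate 2, 16 with limma on FPKM at either pseudocount, 6 and 5 without control replicates 1 and 2, 6 with the replicate block, 1 with the GC and length correction, alone or with the block, and 7 with it without control replicate 1. The other alternatives each lost 1 to 3. At this depth, 31211419 to 33923036 counts per library, changes under 1.5-fold are often missed with 2 libraries per group: in simulated data 78% of genes changed 1.5-fold were recovered.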

Other observations

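The 7 gene lists and the genes named in this part and the tests of the class with 5′ terminal oligopyrimidine tracts, of NBEA and of mesenchymal-like cells were chosen after the results were seen. Camera p-values of these 7 lists were adjusted over them alone, apart from the 28 fixed list tests. Adjusted values of the later and the fixed lists are therefore not comparable. Lists that extend a fixed list, such as further ribosomal protein or kinetochore genes, use the same libraries and are not an independent test of it. Beyond the fixed ribosomal protein list, 45 of 53 other cytosolic ribosomal protein mRNAs rose and 0 fell (median log2 fold change 0.37). All 16 measured mRNAs known for a 5′ terminal oligopyrimidine tract, the element that couples translation to mTOR, but encoding no ribosomal protein also rose (median 0.30). They include the elongation factor EEF2 (0.51), EEF1B2 (0.39), EIF4B (0.36) and RACK1 (0.32). Host genes of small nucleolar RNAs, many of which carry the same element, rose in 12 of 14 cases and fell in 0 (median 0.56), for example GAS5 (0.73) and SNHG8 (0.78). Mitochondrial ribosomal proteins did not follow, with 6 of 77 higher and 3 lower (camera adjusted p = 0.205; 13 and 13 with the GC and length correction, 0 and 2 without knockdown replicate 1, 1 and 2 without knockdown replicate 2, and 13 and 5 without control replicate 2). Without knockdown replicate 1 the numbers higher were 25, 5 and 8, and without knockdown replicate 2 they were 25, 6 and 8. Camera gave adjusted p = 6.12e-28, 7.85e-12 and 4.84e-12 for the first 3 of these lists at the preset correlation. With an estimated correlation, adjusted p = 0.0839 for each of them, and limma on log2(FPKM + 1) called 27, 7 and 9 of their genes higher.

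Kinetochore and cytokinesis genes outside the fixed list fell in 21 of 30 cases and rose in 0 (median -0.31; 12 without knockdown replicate 1 and 10 without knockdown replicate 2). Targets of YAP and of serum response factor, which report on the actin cytoskeleton, had 14 of 29 lower and 2 higher (median -0.33). Among the lower ones were the myosin kinase MYLK (-1.44), ANLN (-1.30) and the calponin CNN2 (-1.31). The higher ones were TPM2 (0.60) and SRF itself (0.25), so the list did not move in one direction. TAGLN (0.46) did not pass the test, nor did CTGF (1.69) and CYR61 (-0.60), at a mean of 0.326 and 1.99 CPM. Without knockdown replicate 1, 8 were lower and 0 higher, and without knockdown replicate 2, 9 and 1, and without control replicate 1, 13 and 1. At the preset correlation camera gave adjusted p = 9.19e-12 and 3.64e-06 for these lists, and both calls were lost with an estimated correlation (adjusted p = 0.0839 each). Collagen genes had 10 of 26 lower and 2 higher (camera adjusted p = 3.97e-04, and 0.235 with an estimated correlation). COL6A3 (-1.45) and COL1A1 (-1.35) were lower and COL5A2 (0.97) was higher. Their median was -0.371, and from -0.440 to -0.292 with each library left out in turn. This list takes in members of the fixed mesenchymal and matrix lists, such as COL1A1, COL3A1 and COL4A1, and is not independent of those lists. MYCN itself was 5375 ± 69.8 CPM in the control and 4446 ± 76.3 CPM in the knockdown (log2 fold change -0.27, edgeR adjusted p = 5.20e-05, n = 2 per group), and its neighbour DDX1 had a log2 fold change of 0.10 (adjusted p = 0.283), and was called higher without control replicate 1 (adjusted p = 0.0058) and with the GC and length correction, alone (0.00232), with the replicate block (0.00699) and without control replicate 1 (0.00107). MYCNOS, which overlaps MYCN, was also lower (log2 fold change -0.22, edgeR adjusted p = 0.0224, and -0.26 after the GC and length correction). The MYCNOS call was lost with upper quartile scaling (edgeR adjusted p = 0.0887) and with the replicate block (0.0642). Reads from the bases that MYCN and MYCNOS share cannot be told apart. The MYCN log2 fold change was -0.299 without knockdown replicate 1 and -0.259 without knockdown replicate 2. Its call was lost in both fits, where the spread is estimated from the control pair alone. MB21D2, another gene with a Mab-21 domain, fell from 24.3 ± 1.03 to 7.95 ± 1.17 CPM (log2 fold change -1.61, adjusted p = 1.22e-10), and LINC02593, which lies beside SAMD11 on chromosome 1, rose with a log2 fold change of 2.52. Of 253 windows of 10 Mb, 1 had a median fold change, after the GC and length correction, apart from random gene sets (chromosome 19, 50000001 to 60000000, 186 genes, median 0.115, permutation adjusted p = 0.0253).

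In the G2/M list 27 of 30 genes and in the matrix list 20 of 29 were lower in the knockdown, and neither list passed camera with an estimated correlation (adjusted p = 0.288 and 0.207, or 0.185 and 0.14 after the GC and length correction). A GC and length trend as the whole cause is argued against, since after the correction the medians were -0.398 for the G2/M list and -0.450 for the matrix list, close to -0.445 and -0.489 before it. A single aberrant control library is argued against for the G2/M list, since its mean log2 level differed by 0.101 between the controls and by 0.443 between the groups. A smaller share of mesenchymal-like cells in the knockdown cultures may account for the matrix genes and cannot be told apart from lower expression per cell. Of 18 mesenchymal-state genes of at least 5 CPM, 14 were lower by 0.1 or more and 4 were not. CD44 (0.02) and S100A6 (-0.02) were among the 4, but both depended on the setting. After the GC and length correction CD44 was 0.09 and S100A6 -0.21, and with limma on log2(FPKM + 1) they were -0.25 and -0.02. Neuroblasts may also express the mesenchymal-state genes themselves. Whether the knockdown, its hairpin or a slower culture lowered the G2/M and matrix genes stays open, as the design has 1 control hairpin and 1 targeted gene.

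In the ribosomal protein list 29 of 30 mRNAs were higher in the knockdown, and the list did not pass camera with an estimated correlation (adjusted p = 0.197). The GC and length correction, which takes both from the longest annotated transcript, left their median at 0.317. This argues against a trend over those values as the whole cause. Of 10000 random lists matched on level and on the length of the longest annotated transcript, 0% reached the ribosomal median. The highest was 0.137. The 194 genes they were drawn from were longer (median 2459 against 1846 bases) and less abundant (548 against 1330 CPM). The longest annotated transcript also need not be the expressed one. The lists therefore cannot exclude a general gain of short abundant transcripts. A rise of mRNAs with 5′ terminal oligopyrimidine tracts as a class is compatible with the data. Of such mRNAs without a ribosomal protein, 16 of 16 were called higher, though 7 with limma on log2(FPKM + 1). Their median was 0.303, against 0.279 without knockdown replicate 1, 0.308 without knockdown replicate 2 and 0.267 with limma on log2(FPKM + 1). The class hypothesis was found and tested on the same data. Reads shared with ribosomal pseudogenes, the hairpin and culture density were not tested.

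MAB21L1 fell together with its paralog MAB21L2. Reads shared between the paralogs are argued against, since 0% of the 75-base windows of MAB21L1 occur in MAB21L2. Reads from introns of its host NBEA are argued against as well, since NBEA rose (log2 fold change 0.45). A hairpin that also matches MAB21L1 cannot be told apart from an effect of MAB21L2 on its paralog, because the genes share 5 windows of 19 bases (0 of 21 bases) and the hairpin sequences are not given in the sources used here.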
